A study of Mus musculus with 4 samples.

How the data were processed

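Single-cell RNA-seq of hindgut from C57BL/6 mouse embryos and of colon from adults given DSS was analysed, with 1 library for each of 4 groups. The embryonic groups were E14.5, with 25 embryos pooled, E15.5, with a pool of 17, and E18.5, with a pool of 14, and the remaining group was the adult library. Groups came from the titles of the samples. DSS is read here as dextran sulfate sodium, a polysaccharide that injures the colonic epithelium of mice; its dose, the length of the treatment and the number of adult animals are not given in the sources used here. Per the labels' protocols, live cells were sorted after staining for EpCAM, an epithelial surface protein, and CD45, a surface protein of blood leukocytes, and epithelial and mesenchymal cells went into each library. The gates are not given in the sources used here. Per the labels' protocols, adult epithelium was first detached and then treated with TrypLE, whereas adult mesenchyme was digested with collagenase and dispase, so tissue handling differed between adult and embryonic groups as well as stage and treatment. No library of untreated adult colon was analysed here.

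The authors deposited 2 tables for each library. The raw table held whole-number counts of unique molecular identifiers (UMIs) per gene and cell, with cells in columns. The table of normalized values deposited by the authors held the natural log of 1 plus the count per 10000 counts of the same cell, which was checked against the raw table cell by cell. Per the submitters' processing notes, Cell Ranger, Seurat 3.1, R 3.6.2 and the mm10 build of the mouse genome were used; the version of Cell Ranger, the gene annotation and the filters on cells and genes are not given in the sources used here. The tables listed between 16489 and 18578 genes, 19563 in their union and 15547 in all libraries. A gene that a table did not list was treated as having 0 counts there, and leaving out such genes was tried as an alternative. How reads shared by near-identical genes were counted is not given in the sources used here, so values of close paralogs such as Ly6a and Ly6c1, Reg3b and Reg3g, Hspa1a and Hspa1b, the serpins of the Serpina1 family and members of the Saa family are uncertain as to which member they belong to.

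Cells with at least 200 detected genes and at most 25% mitochondrial counts were kept, and every deposited barcode passed. Doublets were scored with Scrublet in scanpy 1.11.5, and the cells with the highest scores were left out, 0.8% per 1000 barcodes. This removed 316 cells at E14.5, 703 at E15.5, 383 at E18.5 and 179 in DSS. Each library was clustered alone, with the 2000 most variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 (igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0). Clusters were named from marker genes fixed before the data were examined, as the cell type with the highest mean scaled marker level among those with at least 3 markers detected in 10% of the cells. A cluster stayed unnamed where another cell type had more markers among its 10 leading genes, or where its median UMI count was low and no marker of its own was among them; this scoring was set after the data were seen. In DSS this kept 2 epithelial-scoring clusters of low depth, 558 cells or 12.3% of the library, out of the epithelial class. At E18.5, 48 epithelial-scoring cells, or 0.735% of the library, stayed unnamed, and none were left out in that way at E14.5 or E15.5.

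Raw counts were summed over the cells of a class in each library and divided by their total and multiplied by 1000000 to give CPM, with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. With 1 library per group no test across replicates was possible, so no p-value is given and no difference has a replicate check. Levels carry exact Poisson 95% intervals and ratios carry conditional binomial 95% intervals, both of which cover counting error only. Shares of genes carry exact binomial 95% intervals, which treat genes as independent draws and cover neither counting error nor variation between libraries. The floor was 3 counts over the class in a library. Against 0 counts a ratio is given as a lower bound computed at this floor. This bound is not a 95% limit, which is lower, as for Muc2 in epithelium at E18.5 over E14.5 (2396 against 2946). Against fewer counts than the floor but more than 0, the counts themselves are used, with the interval. Such ratios are not on the scale of the floor. It was 0.418 CPM in E14.5 epithelium, 0.0366 CPM in E18.5 epithelium, 0.0698 CPM in DSS epithelium, 0.157 CPM in E14.5 fibroblasts, 0.325 CPM in E18.5 fibroblasts and 0.641 CPM in DSS fibroblasts. The epithelial sums held 7173884 UMIs at E14.5, 17193020 at E15.5, 81965459 at E18.5 and 42981111 in DSS; the fibroblast sums held 19096717, 48252938, 9240437 and 4681616.

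Before the data were examined, 22 gene lists were fixed: absorptive, goblet, enteroendocrine, tuft, intestinal stem, fetal regenerative epithelium, YAP target, embryonic growth, hindgut identity, proliferation, host defence, interferon response, antigen presentation, fibrillar matrix, contractile, niche signal, hedgehog response, crypt-base fibroblast, inflammatory fibroblast, complement, dissociation stress and posterior Hox. A member counted as measured with 10 CPM or more in either library compared, and the number at least 2-fold higher or lower was counted. The median log2 ratio of each list with at least 3 measured members was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and this percentile describes these libraries only. Several lists share members, such as Ly6a, Ly6c1, C3, Dpt, Cxcl1 and Saa3.

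Single genes were chosen by a rule that was also fixed beforehand. For each of 4 comparisons it took the 12 genes with the largest log2 ratio on each side after adding 5 CPM, among genes with 50 CPM or more in the higher library, detected in at least 5% of its cells of the class and at a level of at least 0.5 times that in the other main class. Mitochondrial, ribosomal protein, hemoglobin, Y-linked and immunoglobulin genes and those with provisional Gm or Rik names were left out, and Xist was excluded in the same way. The 2 highest and 2 lowest members of each list were added where the list is described. The values of some single genes that these rules select are not reported here. Genes named outside this rule were chosen after their values were seen. Early genes were defined as those with 20 CPM or more at E14.5 and at least 2-fold higher there than at E18.5, and late genes by the reverse. E18.5 cells of a class were split at random into 2 equal sets, one to define early genes and the other as the comparison for DSS, so that counting noise at E18.5 did not enter both ratios. Both sets came from the same library, so any trait of that pool or its handling still entered both ratios. Such a trait can make a gene count both as early and as higher in DSS. All other genes with 20 CPM or more in at least 1 of the 3 libraries were the background. It admits genes through a high level in DSS alone, which raises its share higher in DSS by construction. Those of its genes with 20 CPM or more at E14.5, which could have been early, were added as a background after the data were seen.

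The computations were tested on simulated data. With 200 genes changed 4-fold, all 200 were recovered past 2-fold in each of the 4 comparisons and 0 unchanged genes passed; between 95.3% and 95.7% of the 95% intervals held the true ratio. For early genes, 200 simulated ones were found with 25% of them higher in DSS, which was the simulated share. In both classes, 100 simulations of unchanged libraries gave 0 early genes. The simulated counts held counting error only, without variation between cells, clusters or libraries. Coverage near 95% and the lack of false early genes therefore followed from the design. These simulations check the computations and carry no information on error between libraries.

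Gene positions are those of GENCODE release M21 on GRCm38, the assembly that mm10 names, and 19058 of the 19563 symbols (97.4%) were found there by name. Alternatives were other filters on cells, no doublet removal, other clustering resolutions, a joint clustering, classes from single cells, scaling by the median ratio over genes, the mean over cells of the authors' normalized values, fold thresholds of 1.5 and 3 and other minimum levels; they were listed before the data were examined, and 3 more were added afterwards. Figures were drawn with matplotlib 3.10.9.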

Results

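The transcriptomes of hindgut cells from mouse embryos at E14.5, E15.5 and E18.5 and of colon cells from adult mice given DSS were measured cell by cell, to ask which gene programs of the embryonic colon differ between stages and whether they are active again in the inflamed adult organ. Each group was 1 library, so no difference has a replicate check. The tables held 6287 cells and 58357298 UMIs at E14.5, 9377 cells and 116831693 UMIs at E15.5, 6915 cells and 112084558 UMIs at E18.5, and 4732 cells and 52949155 UMIs in DSS. Median depth was 8273, 10570, 15183 and 10736 UMIs per cell, respectively. The epithelial class held 685, 835, 4023 and 3143 cells in these libraries and the fibroblast class 2040, 4426, 1282 and 609 cells. These numbers follow the sort and carry no information on tissue composition. Epithelial cells came from 2 clusters at E14.5 (the larger, cluster 12, held 502 cells), from 3 at E15.5 (366 cells in cluster 8), from 13 at E18.5 (676 cells in cluster 5) and from 16 in DSS (344 cells in cluster 3). Fibroblasts came from 6 clusters at E14.5 and 7 at E15.5, with cluster 0 the largest in both (556 and 1097 cells), from 4 at E18.5 (545 cells in cluster 11) and from 4 in DSS (226 cells in cluster 16).

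Between E14.5 and E18.5 the comparison addressed which programs differ in the hindgut epithelium before birth. Genes of differentiated epithelial cells were higher at E18.5 and genes of embryonic growth and the cell cycle were higher at E14.5. Muc2, the main gel-forming mucin of the colon (chromosome 7, 141690340 to 141754693, GRCm38), was at 1232 CPM at E18.5 with 0 counts at E14.5, at least 2946-fold higher. Pyy, a hormone of enteroendocrine cells, was at 1143 CPM and at least 2733-fold higher. In the opposite direction, Mdk, which encodes the growth factor midkine, was at 1390 CPM at E14.5 and 4.15 CPM at E18.5, 335-fold higher at the earlier stage (95% interval 301 to 374); its level in E14.5 fibroblasts was 1652 CPM.

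Secretory and absorptive genes were higher at E18.5. All 14 measured goblet genes were at least 2-fold higher at E18.5, led by Muc2 and Clca1 (661-fold, 303 to 1800), and the smallest ratios were 10.9-fold (7.34 to 16.8) for Sytl2 and 8.12-fold (5.90 to 11.5) for Guca2b. Agr2, a protein disulfide isomerase needed for mucin production, stood at 3843 CPM, 128-fold higher (112 to 147). Spink4 was 202-fold higher (166 to 249), and Fcgbp was 585-fold higher (284 to 1455). Of the absorptive genes 11 of 13 were at least 2-fold higher and 0 lower, from Aqp8, a water channel (at least 420-fold), and Muc3 (176-fold, 68.9 to 648) to Krt20 (1.97-fold, 1.72 to 2.27) and Slc51a (1.81-fold, 1.65 to 1.99). Every one of the 8 measured enteroendocrine genes was higher. Beside Pyy, Tph1 was higher by at least 36.5-fold and Cpe was 6.23-fold higher (3.82 to 10.9). No tuft gene reached 10 CPM in either epithelium, so 0 of the list were measured. Other genes with the largest ratios toward E18.5 were Sval1 (768 CPM, at least 1836-fold), Nupr1 (374-fold, 247 to 596), Mptx1 (at least 1011-fold), Lgals3 (224-fold, 145 to 367), Dmbt1 (692-fold, 270 to 2540) and the antimicrobial lectin Reg3b (351 CPM, at least 839-fold). Sval1, Mptx1 and Reg3b were not listed in the E14.5 table.

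Host defence genes were on the same side, with 9 of 9 at least 2-fold higher at E18.5, among them Saa1 (at least 140-fold), Cd14 (4.21-fold, 2.77 to 6.75) and Ccl20 (4.17-fold, 3.08 to 5.78). All 4 measured antigen presentation genes were higher, from H2-K1 (6.20-fold, 5.64 to 6.83) to B2m (2.07-fold, 1.86 to 2.30), as were all 3 interferon response genes, among them Bst2 at 2.33-fold (1.91 to 2.87) and Irf1 at 2.10-fold (1.73 to 2.57). Complement genes were higher in 3 of 3 cases, with Cd55 at 6.03-fold (4.36 to 8.58) and C2 at 3.17-fold (2.32 to 4.45). Of 4 inflammatory genes 3 were higher, and Timp1 was 23.1-fold lower (16.1 to 33.6). Genes known to respond to tissue dissociation lay on the same side: 12 of 17 were at least 2-fold higher at E18.5, led by Nr4a1 (15.2-fold, 12.2 to 19.1) and Zfp36 (12.5-fold, 10.9 to 14.4), whereas the heat shock genes Hspa1a and Hspa1b were 13.1-fold (12.5 to 13.8) and 13.7-fold (13.1 to 14.4) lower.

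Genes of embryonic growth, cell division and matrix were lower at E18.5. Of 14 embryonic growth genes 10 were at least 2-fold lower and 0 higher; Tubb2b was 75.5-fold lower (62.9 to 91.3), and Dlk1 lay at the other end at 1.99-fold higher (1.75 to 2.28). Of 18 proliferation genes 14 were at least 2-fold lower, from Ccnb1 (4.22-fold, 3.81 to 4.67) and Mcm6 (3.70-fold, 3.44 to 3.96) to Mki67 (1.42-fold, 1.30 to 1.56) and Pcna (1.25-fold, 1.13 to 1.37). In the YAP target list 4 of 7 were lower, Ctgf by 32.2-fold (23.1 to 45.5) and Ajuba by 12.8-fold (9.80 to 16.7). All 3 measured fibrillar matrix genes were lower: Postn 43.0-fold (28.6 to 66.7), Fn1 28.0-fold (24.3 to 32.3) and Sparc 14.3-fold (12.6 to 16.3), with 22.7, 121 and 842 CPM in the fibroblasts of the E14.5 library. Beyond the lists, the genes highest at E14.5 were Tff1, a trefoil peptide (341 CPM, 1214-fold, 807 to 1918), Ddah2 (72.7-fold), the tight junction gene Cldn6 (157 CPM, 90.8-fold, 76.2 to 109), Fscn1 (147-fold), Palm3 (66.5-fold), Serpina1a (39.0-fold), Bex1 (978 CPM against 63.0 CPM), Cbln2 (28.4-fold) and Pfn2 (25.7-fold).

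Genes of the fetal regenerative epithelium, which are described in fetal and damaged gut, went both ways. Of 16 measured, 5 were at least 2-fold lower at E18.5 and 3 higher. Basp1 was 31.9-fold higher at E14.5 (26.5 to 38.6), with 634 CPM in fibroblasts. Areg, an EGF receptor ligand, was 17.2-fold higher at E18.5 (13.8 to 21.8) and Plaur 14.7-fold (11.8 to 18.6). The list median was 0.10 log2 units above that of all genes, and its sign without that reference flipped with the scaling. Intestinal stem genes were higher in 4 of 9 cases and lower in 1, with Lrig1 16.5-fold (7.06 to 51.0) and Slc12a2 5.51-fold (4.85 to 6.28) higher, Rnf43 1.29-fold lower (1.10 to 1.52) and Cdca7 5.18-fold lower (4.72 to 5.68). Hindgut identity genes were higher in 4 of 15 cases and lower in 2: Klf4 was 5.11-fold (4.74 to 5.52) and Cdx1 3.78-fold (3.46 to 4.14) higher, and Cdx2 (278 CPM at E14.5 against 92.7 CPM) and Isx 2.21-fold (2.00 to 2.44) lower. Posterior Hox genes, which mark position along the body axis, were at least 2-fold higher in 2 of 5 cases, Hoxb9 by 2.55-fold (2.17 to 3.03) and Hoxa9 by 2.08-fold (1.64 to 2.67). Of genes listed for mesenchyme, contractile genes were higher in 2 of 5 cases, niche signal genes lower in 1 of 3, hedgehog response genes lower in 1 of 2 and crypt-base fibroblast genes lower in 2 of 2, Ly6a by 6.05-fold (5.48 to 6.67) and Cd81 by 3.38-fold.

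Relative to all 8714 genes compared, whose median log2 ratio was -0.11 with CPM and -0.06 with median-ratio scaling, the list medians at E18.5 over E14.5 were 7.07 for goblet, 5.36 for absorptive, 8.09 for enteroendocrine, 4.73 for host defence, -2.02 for embryonic growth, -1.33 for proliferation and -1.38 for YAP target genes. The goblet, absorptive and host defence medians exceeded those of all random lists (percentile 100), and the median of embryonic growth genes lay below all of them (percentile 0). Goblet-like and enteroendocrine-like clusters were named only in later libraries, so these ratios compare mixtures of cell types. Without such clusters and the tuft-like ones, 7 goblet genes were measured, and their median log2 ratio was 2.98 against 6.95. Position along the gut differed too. Clusters high in Hoxb13, which marks the distal end of the gut, held 183 of 685 epithelial cells at E14.5 and 2885 of 4023 at E18.5. All epithelial ratios between these stages, those of posterior Hox genes included, therefore join stage to position along the gut.

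Fibroblasts from E14.5 to E18.5 were compared for the same purpose in the mesenchyme. Fibrillar matrix, inflammatory fibroblast and interferon response genes were higher at E18.5 and proliferation genes were lower. Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), was at 1460 CPM at E18.5 and 10.4 CPM at E14.5, 141-fold higher (122 to 163), with 17.9 CPM in the epithelium of the same library. Ccl2, a monocyte chemoattractant, was 135-fold higher (110 to 168), and Dpt, a matrix protein, 850-fold (332 to 3125). Hmga2, a chromatin protein of embryonic cells, was at 549 CPM at E14.5 and 75.2 CPM at E18.5, 7.31-fold lower (6.76 to 7.90).

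Of the 22 fibrillar matrix genes 21 were at least 2-fold higher at E18.5 and 0 lower, from Dpt and Col15a1 (367-fold, 143 to 1350) to Col5a2 (2.18-fold, 2.10 to 2.27) and Col14a1 (1.17-fold, 1.12 to 1.21). Inflammatory fibroblast genes were higher in 18 of 21 cases and lower in 0, with Il33 at 1.23-fold (1.07 to 1.42) and Has2 1.09-fold lower (0.940 to 1.26) at the other end. All 10 interferon response genes were higher, among them Iigp1, an interferon-inducible GTPase (650-fold, 342 to 1424), Isg15 (151-fold, 64.2 to 469), Bst2 (6.31-fold, 5.40 to 7.39) and Ifitm3 (5.53-fold, 5.33 to 5.73). All 6 antigen presentation genes were higher, from H2-K1 (42.8-fold, 22.8 to 90.5) to Tapbp (5.08-fold, 4.12 to 6.29) and B2m (215 CPM against 59.8 CPM), and all 4 host defence genes, led by Cxcl2 (130-fold, 89.1 to 198) and Cxcl1 (74.2-fold, 61.3 to 90.5). The dissociation genes lay on the same side here too: 12 of 17 were at least 2-fold higher at E18.5, with Zfp36 at 28.1-fold (26.3 to 30.1) and Nr4a1 at 11.1-fold (10.3 to 11.9), and Hspa1a and Hspa1b, at 1794 and 1352 CPM at E14.5, were 15.4-fold and 13.6-fold lower. Other genes far higher at E18.5 were the microfibril gene Mfap5 (256 CPM, 144-fold), Spon2 (320 CPM, 47.4-fold), Abi3bp (184 CPM, 51.0-fold), Aspn (457 CPM, 25.0-fold) and the adhesion molecule Icam1 (261 CPM, 29.5-fold). All of the 12 markers from which fibroblast clusters were named, except Pdgfra, are fibrillar matrix genes, Dpt and Mfap5 among them. The fibrillar matrix result is therefore not independent of how the class was named.

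Contractile genes were higher in 10 of 14 cases and lower in 0, with Lmod1 at 19.9-fold (12.4 to 33.8), Myocd, a transcriptional coactivator of smooth muscle genes, at 16.2-fold (62.0 CPM against 3.82 CPM), Tpm1 at 1.49-fold and Synpo2 1.28-fold lower (1.12 to 1.47). Niche signal genes, mostly Wnt, BMP and related ligands and antagonists of gut mesenchyme, were higher in 5 of 17 cases and lower in 2. Bmp2 was 21.3-fold (17.3 to 26.6) and the BMP antagonist Nog 5.79-fold (4.43 to 7.64) higher, whereas Wnt5a was 2.38-fold (2.21 to 2.56) and Foxl1 2.30-fold (1.93 to 2.74) lower. Hedgehog response genes were within 2-fold in all but 1 of 11 cases, Boc (2.31-fold higher, 1.86 to 2.86). Proliferation genes were at least 2-fold lower in 15 of 18 cases, with Plk1 at 5.39-fold (4.25 to 6.94) and Aurka at 4.82-fold (3.94 to 5.93) lower, Top2a 1.71-fold lower (1.62 to 1.81) and Pcna 1.03-fold higher (0.943 to 1.13). Embryonic growth genes were lower in 5 of 16 cases, led by Hmga1 (10.8-fold, 7.80 to 15.2) and Hmga2, and higher in 2, the imprinted genes Dlk1 (2.34-fold, 2.27 to 2.41) and Peg3 (2.22-fold, 2.08 to 2.37). Posterior Hox genes were lower in 5 of 7 cases, Hoxa9 by 4.06-fold (3.19 to 5.24) and Hoxd9 by 2.91-fold (2.23 to 3.85). Nnat (884 CPM, 5.70-fold), the stem gene Cdca7 (146 CPM, 5.30-fold), Rpp25l (5.65-fold), the heat shock genes Hspb1 (4.43-fold) and Hsph1 (4.75-fold), Gmnn (4.32-fold), Sap30 (4.50-fold) and the proliferation gene Ube2c (441 CPM, 3.89-fold) were among those most above E18.5 at E14.5.

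In E18.5 fibroblasts the remaining lists were also counted. Fetal regenerative genes were higher in 7 of 11 cases, with Areg at 57.7 CPM (220-fold, 93.8 to 681) and Ereg at 24.5 CPM (156-fold, 52.6 to 761). Intestinal stem genes were higher in 6 of 10 cases, led by Sox9 (8.39-fold) and Cd44 (6.33-fold), and crypt-base fibroblast genes in 3 of 5, with Clec3b at least 111-fold higher. YAP target genes were lower in 3 of 7 cases, with Birc5 at 3.41-fold and Ctgf at 2.90-fold. Of 2 complement genes, Cd55 was 2.38-fold higher and Serping1 1.89-fold. Goblet genes reached 10 CPM in 6 cases, but their fibroblast levels were a small part of the epithelial ones, 71.1 CPM against 5483 for Tff3 and 40.1 CPM against 2736 for Spink4. The 2 tuft genes above the minimum were Ptgs1 (30.4 CPM) and Dclk1 (17.0 CPM), which had 0.122 and 0.0732 CPM in the epithelium. Relative to all 8831 genes, whose median log2 ratio was -0.14 with CPM and -0.03 with median-ratio scaling, list medians were 2.61 for fibrillar matrix, 3.99 for inflammatory, 4.93 for interferon response, 1.82 for contractile, -1.19 for proliferation, -0.19 for embryonic growth (percentile 15.52) and 0.34 for niche signal genes (percentile 92.9).

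At E15.5 part of these differences was present. In the epithelium 12 of 12 goblet genes were already at least 2-fold above E14.5, and Agr2 stood at 607 CPM and Spink4 at 1310 CPM. By contrast, absorptive genes were higher in 2 of 6 cases, and 0 of 18 proliferation genes differed by 2-fold. Mdk was at 373 CPM at E15.5, between its E14.5 and E18.5 levels, and 5 of 14 embryonic growth genes were lower than at E14.5. In fibroblasts 12 of 18 fibrillar matrix genes were higher at E15.5 than at E14.5, whereas inflammatory genes were higher in 4 of 13 cases and interferon response genes in 0 of 4. Cxcl10 was at 18.49 CPM in E15.5 fibroblasts, and Hmga2 was at 348 CPM.

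**Figure D1:**
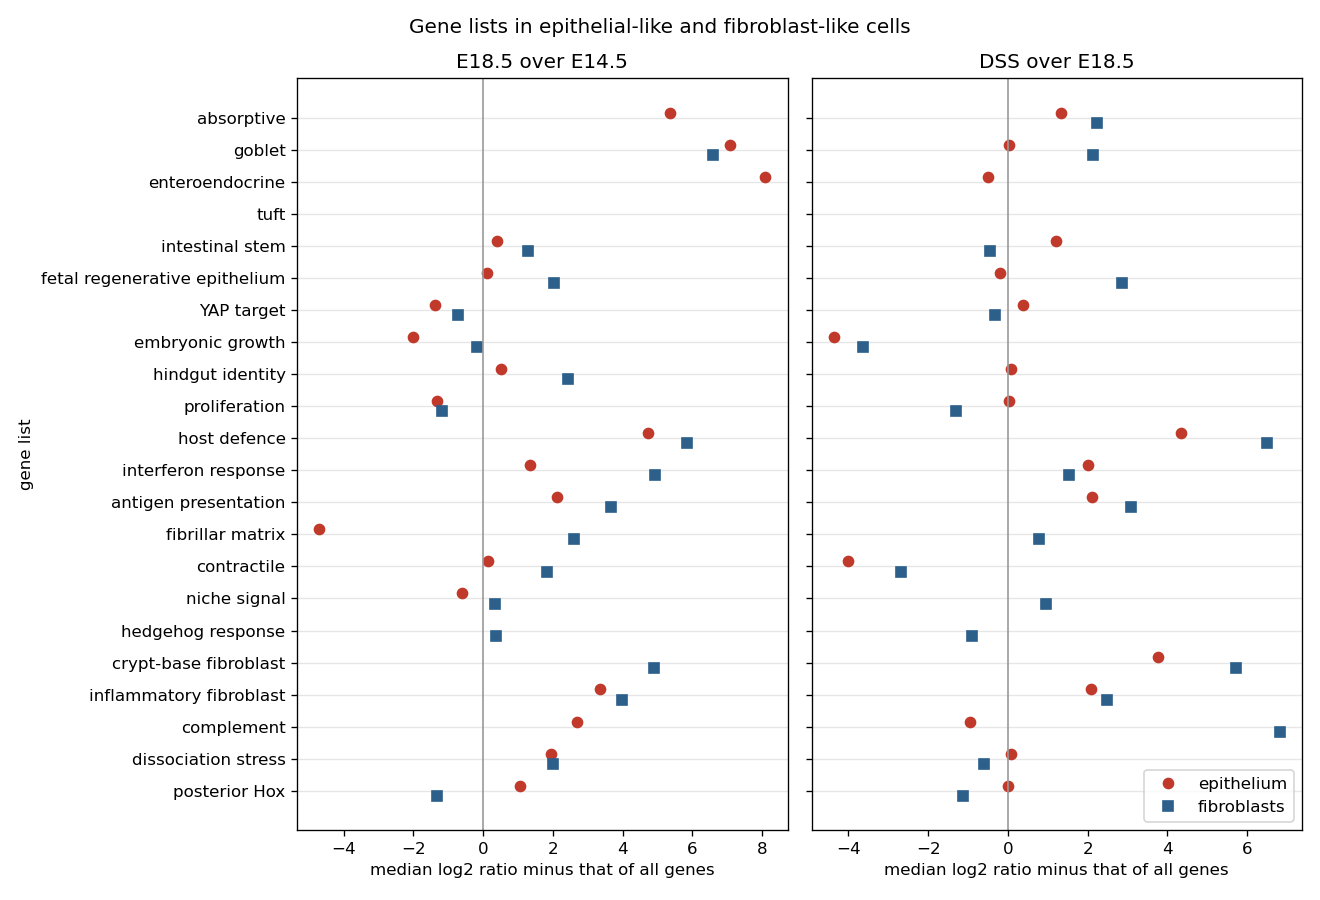
Median log2 ratio of each fixed gene list relative to the median of all genes (x axis, log2 units) for E18.5 over E14.5 and DSS over E18.5, in epithelium and in fibroblasts; lists with fewer than 3 measured members are not drawn. In fibroblasts the embryonic growth list is at -0.19 for E18.5 over E14.5 and at -3.64 for DSS over E18.5, and the complement list is at 6.82 for DSS over E18.5.

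The adult DSS epithelium was compared with E18.5, the latest embryonic stage, to see which genes set the inflamed organ apart. This comparison joins adult age, DSS and tissue handling, which cannot be separated without untreated adult tissue. Host defence and antigen presentation genes were higher in DSS, and embryonic growth genes were lower. Reg3g, a secreted antibacterial lectin (chromosome 6, 78466269 to 78468872), was at 1345 CPM in DSS and 1.44 CPM at E18.5, 934-fold higher (780 to 1129). Ly6a, which encodes the surface protein Sca-1 (chromosome 15, 74994877 to 74998031), was at 691 CPM and 14.49 CPM, 47.7-fold higher (45.0 to 50.6), with 1316 CPM in DSS fibroblasts. Igf2bp3, an RNA-binding protein of embryonic tissue (chromosome 6, 49085223 to 49214957), was at 0.349 CPM in DSS and 95.6 CPM at E18.5, 274-fold lower (166 to 490).

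Host defence genes were at least 2-fold higher in 14 of 17 cases and lower in 1. The highest ratios were those of S100a8, with 2 counts at E18.5 (36.2 CPM in DSS, 1485-fold, 410 to 12270), and Reg3g. S100a8 is also a fixed neutrophil marker, and free RNA from the 22 neutrophil-like cells of DSS was not excluded. At the other end Cxcl1 was 1.59-fold higher (1.44 to 1.76) and Ccl20 2.24-fold lower (2.02 to 2.48). Reg3b reached 8538 CPM, 24.3-fold higher (24.1 to 24.6), and the goblet cell product Retnlb 2031 CPM, 402-fold higher (365 to 444). Pigr, the receptor that carries immunoglobulin A across the epithelium, was at 2077 CPM, 70.9-fold higher (68.1 to 73.9). Antigen presentation genes were higher in 7 of 9 cases, with Cd74, the invariant chain (80.9 CPM, 1106-fold, 508 to 3015), and the immunoproteasome subunit Psmb8 (31.5-fold, 27.6 to 36.2) at the top and H2-D1 (1.30-fold) and H2-K1 (1.14-fold) at the bottom. Interferon response genes were higher in 4 of 7 cases, Ifitm3 by 58.3-fold (53.0 to 64.4) and Isg15 by 26.3-fold (21.3 to 32.7), with Irf1 at 1.93-fold (1.82 to 2.04). Further genes at the top were Plet1 (97.7-fold, 86.7 to 111), Pla2g2a (297-fold, 218 to 414), Lrg1 (129 CPM, at least 3513-fold) and Sptssb (229-fold, 169 to 318).

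Absorptive genes went both ways. Of 17 measured, 9 were at least 2-fold higher and 7 lower: the carbonic anhydrases Car4 (166 CPM, 2269-fold, 1042 to 6186) and Car1 (2181 CPM, 60.3-fold, 58.1 to 62.5) led the higher ones, and the apolipoproteins Apoa4 (0 counts in DSS, at least 304-fold) and Apoa1 (17.4-fold, 15.7 to 19.2) the lower ones. Goblet genes were higher in 4 of 14 cases and lower in 5, with Zg16 14.8-fold (14.6 to 15.1) and Guca2b 4.61-fold higher and Clca1 11.4-fold (10.9 to 11.9) and Tff3 4.89-fold (4.85 to 4.94) lower. Enteroendocrine genes were higher in 3 of 8 cases and lower in 4; Chga was 3.81-fold and Tph1 2.50-fold higher, and Sst, the somatostatin gene, 84.7-fold (69.7 to 104) and Cck 8.91-fold lower. Stem genes were higher in 5 of 11 cases and lower in 0, led by Smoc2 (26.4 CPM, 10.5-fold, 9.06 to 12.3) and Prom1 (5.92-fold, 5.63 to 6.23), with Slc12a2 1.32-fold and Rnf43 1.56-fold lower.

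Embryonic genes showed the opposite. Of 11 embryonic growth genes 10 were at least 2-fold lower in DSS and 0 higher, from Igf2bp3 and Sox11 (2 counts in DSS, 232-fold, 63.9 to 1915) to Igf2bp2 (3.83-fold, 3.58 to 4.10) and Hmga1 (1.23-fold, 1.12 to 1.35). Other genes far above DSS at E18.5 were the trypsin inhibitor gene Spink1 (9728 CPM, 33.3-fold, 32.7 to 33.8), Serpina1b (179 CPM, 1921-fold, 750 to 7053), Nrn1 (138-fold), Gatm (347 CPM, 50.3-fold), Folr1 (285-fold), Mptx1 (40.8-fold), Mamdc4 (408-fold), Gpx3 (49.0-fold), Meltf (at least 898-fold) and the endocytic receptor gene Cubn (72.0-fold). Fetal regenerative genes were higher in 3 of 13 cases and lower in 4. Ly6c1, a neighbour and paralog of Ly6a (chromosome 15, 75044018 to 75048830), was at 45.7 CPM and 416-fold higher (219 to 911), with 340 CPM in DSS fibroblasts, whereas Plaur was 2.88-fold (2.76 to 3.01) and Gja1 3.34-fold (2.79 to 4.02) lower. Complement genes were higher in 1 of 4 cases, C3 at 2.75-fold (11.1 CPM against 3665 CPM in DSS fibroblasts), and lower in 2, one of them C2 at 5.71-fold.

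Proliferation genes did not differ by 2-fold in 18 of 18 cases, with Plk1 at 1.37-fold higher and Pcna at 1.79-fold lower as the ends. YAP target genes were within 2-fold in all 5 cases, from Cyr61 (1.43-fold higher) to Tead1 (1.99-fold lower), and hindgut identity genes in 14 of 15, the exception being Foxa3 (2.32-fold lower, 2.19 to 2.46). Of 5 posterior Hox genes 1 was lower, Hoxa10 by 2.13-fold. Dissociation genes were higher in 2 of 17 cases, Hspa1a by 7.53-fold (7.23 to 7.85) and Hspa1b by 4.48-fold, and lower in 4, with Junb at 2.49-fold and Egr1 at 2.16-fold; 3 were higher and 1 lower with median-ratio scaling, and 2 higher and 1 lower with the mean over cells. Across all 8059 genes the median log2 ratio was -0.24 with CPM and -0.01 with median-ratio scaling. Of the genes differing by 2-fold, 34.1% were higher in DSS with CPM, 55.3% with median-ratio scaling and 43.1% with the mean over cells. The uncorrected medians of the goblet, enteroendocrine, YAP target, hindgut identity, proliferation and dissociation lists changed sign with the scaling. Relative to all genes, medians were 4.34 for host defence (percentile 100), -4.37 for embryonic growth (percentile 0), -0.20 for fetal regenerative (percentile 9.80), 2.00 for interferon response, 2.12 for antigen presentation, 1.32 for absorptive and 1.20 for stem genes.

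**Figure D2:**
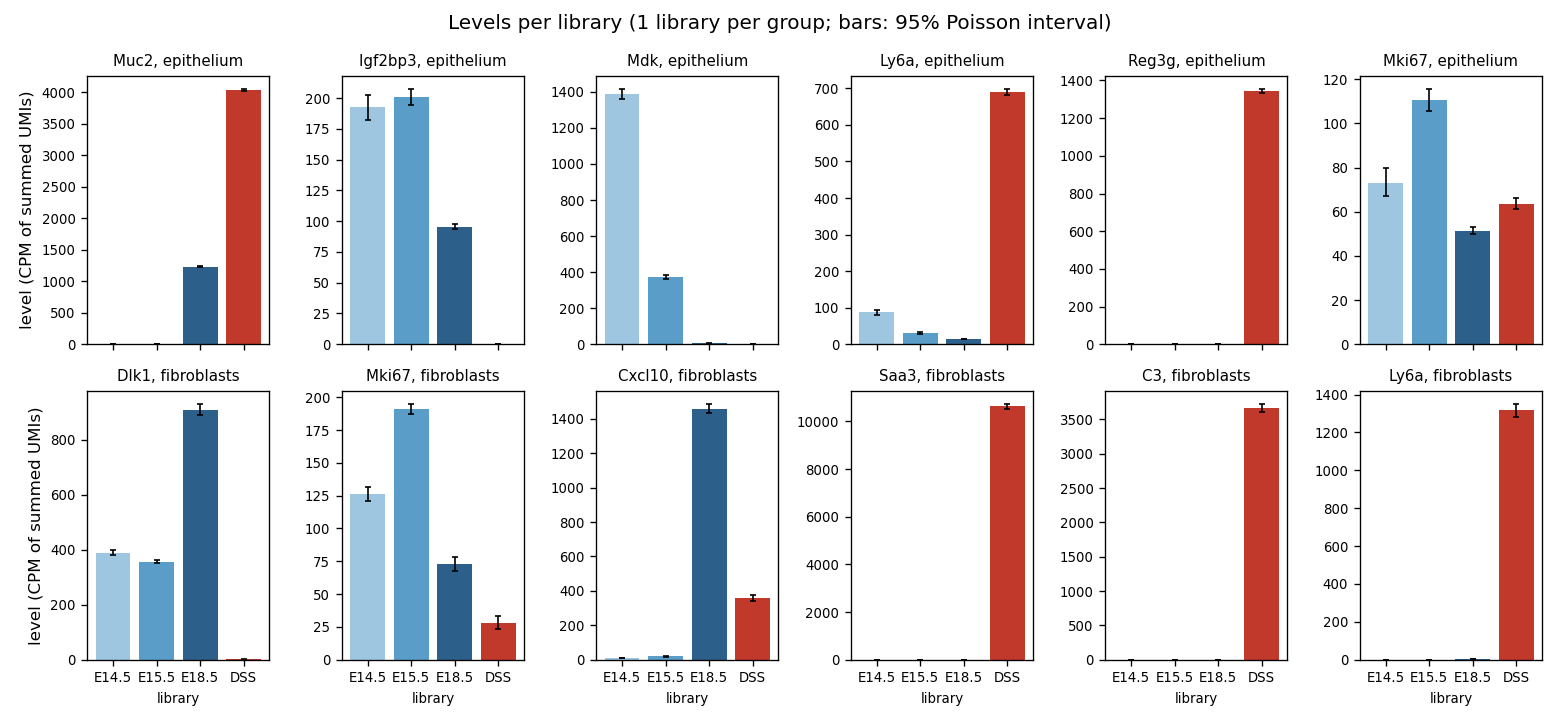
Levels of single genes in CPM in the 4 libraries, for epithelium and fibroblasts; bars are sums over the cells of the class in 1 library and error bars are exact Poisson 95% intervals that cover counting error only. Mdk is at 1390 CPM in E14.5 epithelium and 4.15 CPM at E18.5, and Saa3 is at 10628 CPM in DSS fibroblasts.

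In fibroblasts the same comparison of DSS with E18.5 addressed the inflamed mesenchyme, again with adult age and handling joined to the treatment. Complement and inflammatory fibroblast genes were higher in DSS. Saa3, an acute-phase serum amyloid protein (chromosome 7, 46711998 to 46715700), was at 10628 CPM in DSS against 2 counts at E18.5, a ratio of 49102 (13592 to 405458), with 26.9 CPM in DSS epithelium. C3, the central complement component, was at 3665 CPM against 2 counts (16935-fold, 4687 to 139849). Lcn2, an iron-scavenging protein, was at 1739 CPM, at least 5356-fold higher, and was not listed in the E18.5 table. Dlk1, an imprinted gene of embryonic mesenchyme (chromosome 12, 109452823 to 109463336), was at 0.641 CPM in DSS and 909 CPM at E18.5, 1418-fold lower (485 to 6877).

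All 10 complement genes were at least 2-fold higher in DSS, among them Cfd (275 CPM, at least 847-fold), C4b (713 CPM, 244-fold, 168 to 371), C1s1 (651 CPM, 73.3-fold, 58.9 to 92.5), Serping1 (14.2-fold, 13.2 to 15.2) and Cd55 (8.37-fold, 7.41 to 9.49). Inflammatory fibroblast genes were higher in 27 of 31 cases and lower in 1, Cxcl10 (4.07-fold, 3.87 to 4.28); Icam1 was at 257 CPM against 261 CPM. Mmp3, a matrix-degrading protease, was at 634 CPM (488-fold, 279 to 945). Host defence genes were higher in 15 of 15 cases, with Cxcl2 (933 CPM, 5.07-fold) and Cxcl1 (1838 CPM, 4.34-fold) the smallest ratios, but the count includes epithelial products such as Reg3g (42.1 CPM against 1345 in epithelium) and Reg3b (522 CPM against 8538), for which free RNA was not excluded. Crypt-base fibroblast genes were higher in 14 of 15 cases, from C3, Ly6c1 (340 CPM against 2 counts, 1573-fold, 435 to 13001) and Pi16 (311 CPM, 719-fold, 280 to 2644) to Cd34 (4.52-fold, 4.07 to 5.01), and Cd81 was 2.99-fold lower (2.79 to 3.21). Ly6a was at 1316 CPM against 2.38 CPM (553-fold, 365 to 883). Antigen presentation genes were higher in 7 of 8 cases, H2-K1 by 40.0-fold (34.8 to 46.2) and H2-D1 by 22.6-fold (20.3 to 25.1), with Tap1 at 1.20-fold (0.988 to 1.45). Interferon response genes were higher in 8 of 14 cases, Zbp1 by 31.4-fold (18.7 to 57.1) and Ifi47 by 5.77-fold (3.65 to 9.39), and lower in 2, Iigp1 by 3.29-fold and Irf1 by 2.30-fold. Serpina3n (3142 CPM, 581-fold), Hp (582 CPM against 1 count, 5379-fold, 965 to 212517) and the metallothionein Mt2 (4574 CPM, 63.8-fold) were also among the 12 genes chosen for their ratio.

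Growth, contractile and cell cycle genes were lower in DSS fibroblasts. Every one of the 14 measured embryonic growth genes was at least 2-fold lower, from Dlk1 and Igf2bp3 (70.2-fold, 27.3 to 258) to Grb10 (2.86-fold, 2.61 to 3.15) and Tubb2b (2.11-fold, 1.79 to 2.51). Contractile genes were lower in 13 of 15 cases, with Myocd at 0 counts (at least 96.8-fold) and Cnn1 31.3-fold lower (15.1 to 78.4), and Synm was 14.4-fold higher (8.04 to 28.1). Proliferation genes were lower in 16 of 17 cases, led by Cdk1 (6.65-fold, 5.11 to 8.80) and Rrm2 (6.03-fold, 4.32 to 8.63), with Tk1 at 1.37-fold. Hedgehog response genes were lower in 6 of 12 cases, with Hhip at 7.89-fold (5.55 to 11.6) and Foxf1 at 6.92-fold (6.11 to 7.86), and higher in 1, Cdon at 2.42-fold. Niche signal genes were higher in 9 of 21 cases and lower in 4: Grem1, a BMP antagonist, was at 389 CPM (71.9-fold, 54.3 to 97.2) and Fgf7 at 68.4 CPM (15.4-fold, 11.1 to 21.9), whereas Nog was 26.6-fold (10.2 to 98.5) and Dkk2 12.3-fold (4.65 to 46.0) lower. Other genes far above DSS at E18.5 were Col6a4 (48.4-fold), Igfbp2 (137 CPM, at least 214-fold), the fibrillin gene Fbn2 (462 CPM, 38.6-fold), Mdk (1501 CPM, 26.0-fold), CT010467.1 (8023 CPM, 22.6-fold), Asb4 (47.4-fold), Nnat (48.4-fold), Actg2 (29.6-fold), Sema3a (57.4-fold), Sox11 (24.0-fold) and the imprinted gene Mest (20.2-fold).

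Fibrillar matrix genes were higher in 8 of 22 cases and lower in 0, with Dpt at 1152 CPM (6.46-fold, 6.12 to 6.84) and Eln at 734 CPM (4.38-fold, 4.12 to 4.65), and Col6a2 1.43-fold lower. Fetal regenerative genes were higher in 11 of 15 cases, led by Ly6c1 and Ly6a, and lower in 1, Basp1 at 2.16-fold. Intestinal stem genes were higher in 1 of 10 cases, Cd44 at 4.49-fold, and lower in 4, with Nkd1 at 9.15-fold. YAP target genes were higher in 1 of 6 cases, Axl at 7.61-fold, and lower in 1, Birc5 at 2.49-fold. Dissociation genes were higher in 3 of 17 cases, Hspa1a at 3.18-fold and Hspa1b at 2.31-fold among them, and lower in 7, with Btg2 at 4.25-fold and Socs3 at 3.57-fold; with median-ratio scaling 5 were lower and with the mean over cells 4, and 3 were higher under both. Posterior Hox genes were lower in 3 of 4 cases, with Hoxd11 at 3.45-fold, but their median of -1.29 turned to 0.16 with the mean over cells. Epithelial products in DSS fibroblasts were again a small part of their epithelial level, as for Zg16 (91.0 CPM against 3434) and Car1 (75.6 CPM against 2181). The median log2 ratio of all 9013 genes was -0.15 with CPM and 0.03 with median-ratio scaling, and 44.4% and 55.8% of the genes differing by 2-fold were higher in DSS under these scalings, against 52.6% with the mean over cells. Relative to all genes, list medians were 6.82 for complement, 2.50 for inflammatory, 5.73 for crypt-base, -3.64 for embryonic growth, -2.69 for contractile and -1.30 for proliferation genes.

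Whether early embryonic genes were active in the inflamed adult was addressed with genes at least 2-fold higher at E14.5 than at E18.5. In the epithelium 34 of 992 early genes were at least 2-fold higher in DSS than at E18.5, or 3.43% (exact binomial 95% interval 2.39 to 4.76), and 220, or 22.2%, were at least 2-fold lower. Ly6a led the higher ones, at 87.7 CPM at E14.5, 30.3 CPM at E15.5, 14.49 CPM at E18.5 and 691 CPM in DSS. Next came the atrial myosin light chain gene Myl7 (22.3 CPM at E14.5, 3.31 CPM at E18.5 and 43.9 CPM in DSS), Ly6e (40.3, 17.1 and 197 CPM), Hspa1a (450, 34.3 and 258 CPM) and Fblim1 (22.4, 5.60 and 43.4 CPM). No minimum level in DSS was set, so the 34 include genes scarcely detected there, such as Ppp2r2b (0.163 CPM in DSS) and Fzd2 (1.65 CPM). Both ratios use the E18.5 library, where Hspa1a had its lowest level over all cells of any library (44.1 CPM). The share higher in DSS among all other genes was 5.53% (4.96 to 6.15), and among late genes it was 9.58% (7.90 to 11.5). Among the other genes with at least 20 CPM at E14.5 it was 1.67% (1.32 to 2.09), so with E18.5 as the comparison the early genes lay below one background and above the other. For early genes taken from E15.5 the percents were 2.44 (1.45 to 3.83) and 1.78 (1.44 to 2.18), with overlapping intervals.

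Fibroblast early genes were more often lower in DSS. Of 865, 298 or 34.5% were at least 2-fold lower than at E18.5 and 32 or 3.70% (2.54 to 5.18) were higher, with Hspb1, Usp50 and G0s2 in the lead. Hspb1 stood at 305 CPM at E14.5, 68.8 CPM at E18.5 and 471 CPM in DSS. Usp50, 1810009A15Rik, Hspa1a, Hspa1b, Hsph1 and Rpp25l were among the higher early genes of both classes. From E14.5 through E15.5 and E18.5 to DSS, Usp50 was at 35.9, 14.0, 13.9 and 98.3 CPM in fibroblasts. In epithelium it was at 54.8, 23.3, 18.8 and 69.3 CPM. A difference between whole libraries was not separated from renewed activity of early genes in either class. The share higher in DSS was 14.6% (13.7 to 15.4) among all other genes, 5.94% (5.30 to 6.62) among those with at least 20 CPM at E14.5 and 19.7% (17.1 to 22.6) among late genes. If early genes and genes higher in DSS were independent lists, 115 genes would be shared in fibroblasts and 51.8 in epithelium, against 32 and 34 found. Among genes with at least 20 CPM at E14.5, the only ones that can be early, the same product is 48.54 in fibroblasts and 19.71 in epithelium, so the epithelial count lies below one value and above the other. With E15.5 in place of E18.5 as the comparison, 12 epithelial genes were found, below both products (130 and 55.0). The percents in both classes moved by over 1.5 times with a fold threshold of 1.5, with median-ratio scaling and with E15.5 as the comparison. A fold threshold of 3 moved only the epithelial percent that far.

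**Figure D3:**
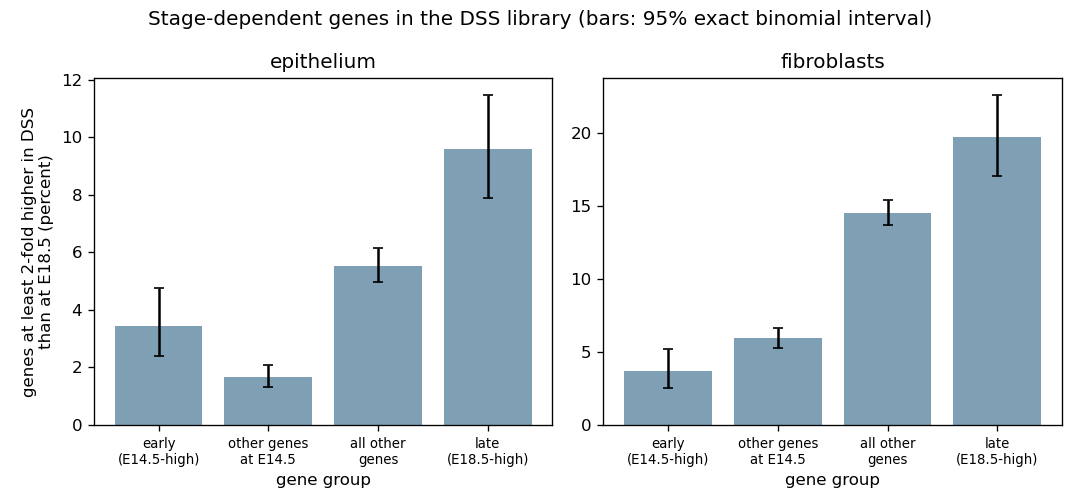
Percent of genes at least 2-fold higher in DSS than at E18.5 (y axis) among early genes, other genes with 20 CPM or more at E14.5, all other genes and late genes, in epithelium and fibroblasts. Error bars are exact binomial 95% intervals that treat genes as independent draws and do not cover variation between libraries. In fibroblasts early genes are at 3.70% and all other genes at 14.6%; in epithelium early genes are at 3.43%, between 1.67% and 5.53%.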

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

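The tests of free RNA and of position along the gut were chosen only after the results they bear on were seen. Those of dissociation stress, of a fetal program and of an interferon response were set before their own outcomes were known. They too address patterns that had already been observed and were not part of the design fixed beforehand.

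Between E14.5 and E18.5, the medians of epithelium and fibroblasts had opposite signs and were both at least 0.5 log2 units from all genes in 2 gene lists with 3 or more measured members in each. The median log2 ratio of fibrillar matrix genes relative to all genes was -4.70 in epithelium (3 members) and 2.61 in fibroblasts (22 members), and the difference was not tested. For posterior Hox genes it was 1.07 in epithelium (5 members) and -1.34 in fibroblasts (7 members), and the difference was not tested. Hoxb13, a member of this list, was at 40.8 CPM in E14.5 and 79.3 CPM in E18.5 epithelium. Within Hoxb13-high clusters it was at 108 and 106 CPM, but the clusters were grouped by Hoxb13 itself. These clusters held 183 of 685 epithelial cells at E14.5 and 2885 of 4023 at E18.5. The epithelial value thus joins stage to position along the gut. From E18.5 to DSS the complement list had a median of -0.95 in epithelium (4 members) and 6.82 in fibroblasts (10 members); the difference was not tested. Cells outside the comparisons were seen in DSS alone among the 4 libraries: 22 neutrophil-like cells, 27 lymphatic endothelial-like cells and an unnamed cluster of 74 cells led by H2-Aa, H2-Eb1, Igkc and Lyz2.

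Inflammatory and interferon genes were higher in E18.5 than in E14.5 fibroblasts, with a median log2 ratio of 4.32 over 31 members, and immediate early genes were higher too (1.88 over 11 genes). Between the least stressed E18.5 fibroblasts (425 cells) and the most stressed E14.5 fibroblasts (678 cells), immediate early genes had a median of -0.49, while that of the inflammatory and interferon genes was 3.38 and 28 of 31 were at least 2-fold higher. This argues against dissociation stress, as measured by immediate early genes, as the whole cause. Free RNA would add similar UMIs to every cell, but the median log2 ratio of UMIs per fibroblast over UMIs per epithelial cell at E18.5 was 4.58, with Cxcl10 at 1460 CPM in fibroblasts, 1535 CPM in pericyte-like cells and 17.9 CPM in epithelium. A difference between stages stays open as an untested explanation, as does any condition of this 1 pool of embryos, and either may underlie the pattern.

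Ly6a was higher in DSS than in E18.5 epithelium. Free RNA from fibroblasts is argued against, since Ly6a UMIs per epithelial cell were 93.4% of those per fibroblast, whereas the highest such percent among 12 fibroblast markers was 0.225%. When DSS epithelial cells were split within clusters by their Ly6a share into 1413 high and 1730 low cells, 4 of 8 interferon response genes, or 50%, were at least 1.5-fold higher in the high cells, led by Isg15 (log2 ratio 1.46) and Zbp1 (1.35), while Ifitm3 was at -0.71. This lies just at the bound set for an interferon response. The share of all genes at least 1.5-fold higher in the high cells was not computed. The 50% therefore does not decide whether an interferon response goes with Ly6a. A fetal regenerative program was not decided, as 3 of 11 members, or 27.3%, were higher, of which Ly6c1 (3.47) is a paralog that can share reads with Ly6a. Adult age and DSS remain joined in this comparison.

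In epithelium 4 fetal regenerative genes, Basp1, Msln, Clu and Ly6a, were higher at E14.5 than at E18.5, with a median log2 ratio of 3.05; they were picked for this direction from a list of 16 measured genes, of which 5 were at least 2-fold lower at E18.5 and 3 higher, with a list median of -0.02 for E18.5 over E14.5. A larger share of Hoxb13-high cells (Hoxb13, chromosome 11, 96194316 to 96197447, marks the distal end of the gut) is argued against, because Hoxb13-high clusters held 183 of 685 epithelial cells at E14.5 and 2885 of 4023 at E18.5, and the median was 3.71 within them and 3.74 within the remaining ones. Free RNA from mesothelial cells is argued against for Msln and Clu, whose UMIs per epithelial cell were at 312% and 182% of the mesothelial level, against at most 0.451% for 6 other mesothelial markers. The age of the embryos is a candidate explanation that was not tested apart from the library. Ly6a itself was at 182 CPM in Hoxb13-high and 34.4 CPM in Hoxb13-low clusters at E14.5, and at 928 and 155 CPM in DSS.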

How the results depend on the processing

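The alternatives for goblet genes without secretory clusters, for genes missing from a table and for low-depth DSS clusters were chosen only after the data were seen. Of 158 alternative values for the 10 main results, 143 stayed close to the reported value, 15 moved and 0 reversed. For early genes a reversal was judged against all other genes only. Counts of 11 absorptive genes, 5 embryonic growth genes in fibroblasts and 5 niche signal genes became 7, 3 and 3 with a minimum level of 50 CPM (absorptive, embryonic growth) or a fold threshold of 3 (niche signal), and a fold threshold of 3 also left 3 embryonic growth genes; both settings admit fewer genes by construction. Without goblet-, enteroendocrine- and tuft-like clusters, 7 of 7 measured goblet genes were higher at E18.5, against 14 of 14; the other 7 were no longer measured, and the median log2 ratio was 2.98 against 6.95. The percent of early genes higher in DSS, 3.43 in epithelium and 3.70 in fibroblasts, became 5.55 and 6.70 with median-ratio scaling, 6.27 and 10.2 at 1.5-fold, 2.24 and 2.51 at 3-fold, and 1.21 and 0.809 with E15.5 as the comparison. In fibroblasts it was 5.52 with a stricter cell filter and 5.25 without doublet removal. Early genes numbered 1867 and 1884 at 1.5-fold, 402 and 199 at 3-fold, against 992 and 865. A looser or stricter fold changes the percents by construction, and so does E15.5 as the comparison, which lies 1 day after the stage that defines early genes; for the other settings the cause was not tested. Under each of them early genes stayed below all other genes in percent. That background admits genes through a high level in DSS alone, which raises its percent by construction. Staying below it is therefore partly fixed by the filter. Against other genes with at least 20 CPM at E14.5, the direction in epithelium depended on the comparison. Epithelial early genes were above these in the reported value (3.43 against 1.67) and below them with E15.5 as the comparison (1.21 against 6.49). Host defence counts in DSS epithelium ranged from 10 to 18, inflammatory counts in DSS fibroblasts from 23 to 29, and embryonic growth counts in epithelium from 8 to 13. Genes near 10 CPM rest on few counts in the smaller sums, above all in DSS fibroblasts. No paired analysis was possible because each group had 1 library.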

Other observations

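The observations on other cell types and on single genes across libraries were chosen only after their values were seen.

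Other cell types of the embryonic hindgut also differed between E14.5 and E18.5, with medians given relative to all genes. Smooth muscle-like cells (538 and 479 cells) had 9 of 15 contractile genes at least 2-fold higher at E18.5 (median log2 ratio 1.78), and 12 of 16 embryonic growth genes lower (-1.04). All markers from which smooth muscle-like clusters were named are contractile genes, so the contractile count is not independent of the naming. Unlike in fibroblasts, 8 of 17 measured proliferation genes of smooth muscle-like cells were higher at E18.5 and 1 was lower. At E15.5 12 of 18 were higher than at E14.5. Of 17 dissociation genes 6 were higher at E18.5 and 4 lower in these cells. Ckm, a creatine kinase of muscle, was at 497 CPM (477 to 518) at E18.5 with 0 counts at E14.5, the metallothionein Mt1 was at 2649 CPM against 3.91 CPM, and the receptor gene Kit was at 4.80 CPM against 107 CPM at E14.5. Cells resembling interstitial cells of Cajal (1778 and 385 cells) had 14 of 15 contractile genes higher at E18.5 (median 2.78), with Cnn1 at 936 CPM against 66.2 CPM and Tagln at 6884 CPM against 530.4 CPM, 15 of 18 proliferation genes lower, and 9 of 17 dissociation genes higher and 3 lower (1.41). When cells were named one by one instead of by cluster, 24 and 3 cells had this name, so the identity of these clusters is uncertain.

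Glia-like cells (397 and 148 cells) had 11 of 17 dissociation genes higher at E18.5 and 2 lower. Fibrillar matrix (11 of 14) and inflammatory genes (6 of 6) were higher too, but Cxcl10 was at 41.6 CPM in these cells against 1460 CPM in fibroblasts, so free fibroblast RNA is not excluded. Apoe, a lipid carrier, was at 1398 CPM against 47.4 CPM, Cryab at 384 CPM against 1.83 CPM and Lmna, a nuclear lamina gene, at 814 CPM against 14.3 CPM. In mesothelial-like cells (285 and 51 cells by cluster, 85 and 3 one by one) 12 of 12 interferon response genes (median 3.34), 7 of 7 antigen presentation genes (3.56), 12 of 16 fetal regenerative genes (1.91) and 9 of 14 inflammatory genes (2.34) were higher at E18.5, beside 6 of 17 dissociation genes with 3 lower, and Crip1 was at 3506 CPM (3309 to 3712) against 28.3 CPM. Goblet gene CPM was also at least 2-fold higher at E18.5 in all 4 of these cell types (7 of 7 in glia-like, 4 of 5 in mesothelial-like and 5 of 5 in the others), which is not taken as a difference of these cells: the epithelial gene Spink1 was at 110 CPM in smooth muscle-like and 112 CPM in glia-like cells at E18.5, against 9728 CPM in epithelium, so free epithelial RNA is not excluded.

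Some genes differed between libraries over all cells. Rpgrip1 was at 143 CPM at E14.5 and at 28.6, 29.6 and 16.6 CPM at E15.5, E18.5 and in DSS. Hspa1a was at 1336, 811, 44.1 and 280.2 CPM in the same order, and CT010467.1 at 667, 759, 2692 and 458 CPM. At E18.5 CT010467.1 was at 8023 CPM in fibroblasts, 7423 in smooth muscle-like cells, 6686 in glia-like cells and 1552 in epithelium. At E14.5 these classes were at 669, 509, 435 and 703 CPM. Its ratio in fibroblasts is thus not particular to them, and the cause was not tested. The Y-linked genes Ddx3y and Eif2s3y were at 26.6 and 34.0 CPM at E14.5, 27.5 and 31.8 CPM at E15.5 and 22.9 and 25.8 CPM at E18.5, and the DSS table listed neither of them, nor Uty or Kdm5d. The sex of the animals is not given in the sources used here, so for genes that differ between sexes the comparison of DSS with the embryos is joined to this difference too.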
